A study of Schizosaccharomyces pombe with 30 samples.

How the data were processed

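Fission yeast (Schizosaccharomyces pombe) cells in log phase, grown in rich medium at 30 °C per the labels' protocols, were profiled on 30 Agilent arrays with 60-base probes in 2 colours. On 25 expression arrays, RNA depleted of ribosomal RNA and copied into cDNA was compared between a mutant, labelled with Cy5, and wild type, labelled with Cy3. On 1 of these arrays wild-type RNA was in both channels. The other 5 arrays compared DNA from chromatin immunoprecipitation (ChIP, Cy5) with input DNA (Cy3). Chromatin was fixed with 3% paraformaldehyde at 18 °C, with 10 mM dimethyl adipimidate added for Rik1, and sheared to 500 to 1000 bp. Per the labels, the tiling design covers a large part of chromosome 2 with a probe every 50 bp over both strands, which is every 100 bp on each strand. It served the expression arrays and 3 ChIP arrays, and a genome-wide design served the other 2 ChIP arrays. No dye was swapped, so gene-specific dye bias stays in each ratio. Subtracting the array with wild-type RNA in both channels removed it only as far as the bias was the same on that array.

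The deposited scanner files hold, per the file headers, output of Agilent Feature Extraction (version 10.1.1.1 for 6 arrays, 9.5.1.1 for 13 and 9.5.3.1 for 11). The intensity columns used are, per the file headers, the median pixel brightness of each spot and of its local background, with no normalization. A second pair of deposited intensity columns, the processed signals, had been background-subtracted, detrended and dye-normalized by Feature Extraction. The deposited log10 ratio is that of the processed red over the processed green signal, and the deposited p-value is that of the scanner software's error model for this ratio. The authors' series tables hold log2 ratios equal to the scanner's log10 ratio times 3.322. For the expression arrays these tables list only spots whose scanner p-value is under 0.05, from 6535 to 27490 of 45220 spots, so that their column medians (-0.52 to 0.46) describe a selected set and were not used for tests. Direction and scale of these tables were settled by this comparison. The ChIP columns are complete, with medians of 0.114 for Pol II, 0.0849 for H2A.Z, -0.0204 for Rik1, 0.110 for H2A.Z on the genome design and 0.0126 for H2A.Z in dmsc1.

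Probe sequences were matched exactly to the ASM294v3 assembly, because the build behind the coordinates in the files is not given in the sources used here. Of 43993 probes of the chromosome 2 design, 40967 had 1 match, 2816 had several and 210 had none. Matched starts lay at -1800 bp from the file coordinates for 27974 probes and at -900 bp for 11985, and 100% of the placed chromosome 2 probes lay on the strand the file names. The main tiled region spans 999111 to 3048020 on chromosome 2. Of 41551 probes of the genome design, 40396 had 1 match, 1053 several and 102 none. Coordinates are those of ASM294v3 throughout. Whether the array reads the stated strand was checked on wild-type RNA (Cy3), where the median intensity was 1676 over 874 sense strands and 103 over 872 antisense strands of coding genes.

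For the expression arrays, background was corrected with normexp (offset 50) on the median signals, since the mean signals are missing from some of the files, and the ratios were normalized by loess within each array in limma. Control and outlier spots had weight 0 in loess, and outlier spots were then left out. Each annotated gene received a sense and an antisense value, the median over its probes with a single match on that strand, with at least 3 probes. A strand entered the test where at least 0.5 of its probes lay well above background in Cy5 or in Cy3 on at least 2 arrays. This left 874 sense and 869 antisense strands of coding genes, and 948 sense strands of non-coding genes. The decision to count coding genes apart was made after the probes were placed and before any contrast was computed.

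limma (lmFit and eBayes) fitted 1 mean per genotype over all 25 arrays and 20 genotypes, with 5 residual and 2.88 prior degrees of freedom. Tests were two-sided. Each genotype was compared with the wild-type array, and p-values were adjusted by Benjamini-Hochberg per strand with a threshold of 0.05. The 5 residual degrees of freedom come from the 5 genotypes with 2 arrays (dpht1, dpht1dago1, dclr4, drrp6 and dpht1dswi6). The other 14 mutants and the wild type have 1 array each, which is assumed to vary like the replicated ones, so a change in these 14 has no replicate check. The labels do not say whether the 2 arrays of a genotype came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. Replicate arrays had r of 0.75 (dpht1), 0.83 (dpht1dago1), 0.27 (dclr4), 0.90 (drrp6) and 0.45 (dpht1dswi6) over antisense strands, and 0 values were identical. An interaction was the double mutant minus both single mutants plus wild type.

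Gene lists and the rule for named genes were written before the data were examined. The lists were subtelomeric genes, mating-type locus genes, mating-type-specific genes, Tf2 retrotransposons, meiotic targets of the RNA-elimination factor Mmi1, genes with meiotic symbols, stress-response genes, ribosomal protein genes, histone genes, phosphate and iron uptake genes, heterochromatin and RNAi factor genes, small nucleolar and nuclear RNA genes, annotated non-coding RNA genes, and 3 orientation classes. A convergent gene is one whose 3′ end faces the 3′ end of its neighbour on the opposite strand within 1000 bp. List shifts were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and adjusted within strand and genotype. Named genes are, per strand, the 8 highest and 4 lowest changes among those past the threshold with the same direction in every array for replicated genotypes, the 3 highest and 2 lowest for single arrays, the deleted genes and up to 4 members of each list. Where a count of 5 or fewer has members outside this rule, those named were chosen after their values were seen.

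For ChIP arrays the ratio of the processed signals was centred on each array's median with no loess. Per gene, values were averaged within 300 bp of the start and of the end and over the body between. These arrays have no replicate and no test.

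The share of probes well above background ran from 52.9% to 94.99% in Cy5 and from 55.2% to 80.5% in Cy3 over the 25 expression arrays, and median intensities ran from 129 to 1047 in Cy5 and from 109 to 402 in Cy3. The number of arrays limits the precision. Data were simulated from the measured Cy3 signals and the fitted spread, with 200 of the 1743 coding strands changed (2691 strands in the fit). Noise was drawn independently per strand and array, with no dye, slide or scan effect, so the rates below leave such effects out. The fit for drrp6 recovered 7.46% of changes of 1.5-fold, 55.2% of 2-fold and 97.0% of 4-fold. For dalp13, with 1 array, it recovered 1.49%, 29.9% and 83.3%. A true log2 change of 1 was measured as 0.79 in the drrp6 simulation, so folds are understated. Of the 1543 unchanged coding strands 13 (0.842%) were called in the drrp6 simulation and 9 (0.583%) in that of dalp13. These are shares of the unchanged strands and not of the calls.

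Slide and scan were read from the file headers. The headers also name the scanner, which was not fitted. The wild-type array shares its scanner with dpht1 replicate 1, both dpht1dago1 arrays, dpht1dswi6 replicate 1 and clr6-1. All other mutant arrays were read on other scanners, so their differences from the wild-type array hold any difference between scanners. The 25 arrays lie on 16 slides, 9 of which hold more than 1 array, and come from 13 scans, 8 of which hold more than 1. Fixed slide or scan terms leave no residual degrees of freedom, so within-batch differences of single arrays are given, and scan was fitted as a random block. Other choices tried were the processed signals centred on each array's median without loess (both choices changed together), the normexp-corrected signals centred on the median in place of loess, ratios against 0, a minimum of 5 probes, a 2-fold threshold, no filter on dim probes, a replicate block, leaving out each replicate, and 3 alternatives chosen after seeing the data: centring on bright sense probes, antisense probes off other genes, and all annotated genes counted together. Comparisons that share the wild-type array share its chance values, so correlations and covariances between them were set beside 100 simulations of unchanged genotypes. Overlap counts were set only beside the number for independent lists, which does not allow for the shared array.

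Computations used R 4.3.3, limma 3.58.1, statmod 1.5.0, data.table (1.17.8), Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.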

Results

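RNA from both strands of a large part of fission yeast chromosome 2 was measured in 20 genotypes on 25 two-colour arrays, each with the named genotype in Cy5 and wild-type RNA in Cy3. The central genotype, dpht1, lacks pht1, the gene for histone variant H2A.Z. It was also combined with loss of Ago1 (the Argonaute protein of RNAi), Clr4 (the heterochromatin histone methyltransferase), Rik1 (a partner of Clr4, named in the labels without the deletion mark that the others carry), Swi6 (the HP1 protein of heterochromatin), Set1 (a histone methyltransferase) or Cph1. Other mutants lacked the nuclear exosome nuclease Rrp6, the poly(A) polymerase Cid14, the H2A.Z-depositing remodeller Swr1, the histone methyltransferase Set2, or Alp13 and Cph1, subunits of a Clr6 histone deacetylase complex, and clr6-1 carries a mutant deacetylase. The mutants dpht1, dpht1dago1, dclr4, drrp6 and dpht1dswi6 had 2 arrays each, and the other 14 mutants and the wild-type control had 1 each. All changes below are log2 differences from the wild-type array with the standard error of the limma fit. On the 25 arrays, 52.9% to 94.99% of probes were well above background in Cy5 and 55.2% to 80.5% in Cy3. The design addresses whether H2A.Z acts with RNAi and heterochromatin factors to hold down antisense RNA.

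The pht1 gene (SPBC11B10.10c, chromosome 2, 1502203 to 1503444, minus strand, 12 probes) checked the labels. Its sense ratio against wild-type RNA lay between -3.85 and -2.36 (median -3.01) on the 10 arrays whose label says that pht1 is deleted, and between -0.63 and 0.35 (median 0.08) on the other 15. On the deletion arrays 8 to 10 of its 12 probes were still well above background in Cy5. The other 11 genes that the mutant labels name as deleted, or for rik1 name without a deletion mark, had 0 measured probes, and their labels could not be checked this way.

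**Figure D1:**
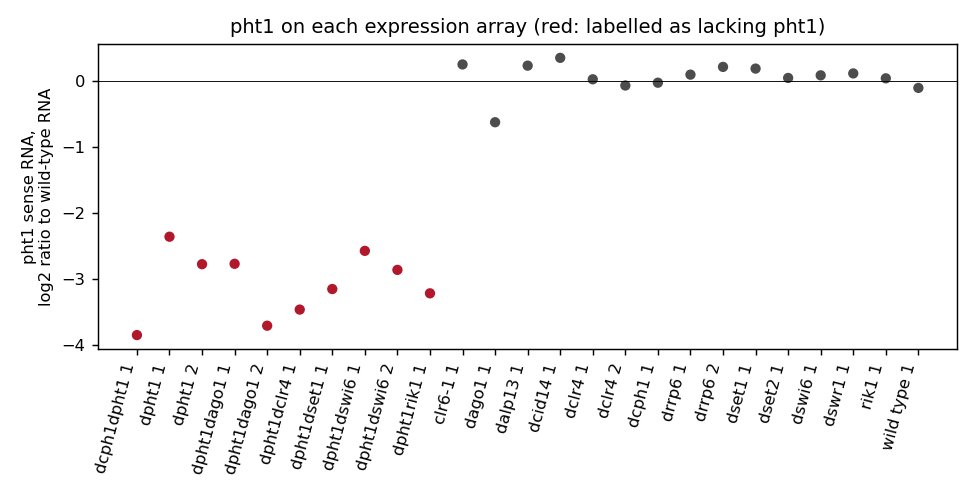
The sense log2 ratio of pht1 (vertical axis, Cy5 over Cy3) is plotted for each of the 25 expression arrays, with arrays labelled as lacking pht1 in red. The 10 red points lie from -3.85 to -2.36 and the 15 others from -0.63 to 0.35.

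Few coding genes were called after loss of H2A.Z alone. On the sense strand limma had 45 strands higher and 70 lower at an unadjusted p under 0.05, against 21.9 each way by chance. Sense RNA of tlh2 (chromosome 2, 4526885 to 4532899), a subtelomeric gene for a RecQ-type helicase, rose by 3.05 ± 0.41 and that of ubi4, a ubiquitin gene, by 1.64 ± 0.21. The preribosome gene cms1 (2109254 to 2110396) fell by 1.85 ± 0.25, the nuclear pore gene ely5 fell by 1.37 ± 0.22, and the deleted pht1 itself fell by 2.46 ± 0.36 (2 arrays against 1; limma adjusted p from 0.0251 to 0.0418 for the 5 genes of 874). On the wild-type array itself cms1 stood at 0.75, and against their own wild-type RNA the dpht1 arrays had -1.37 and -0.82. No antisense strand passed: limma gave 0 higher and 0 lower of 869, with 33 higher and 8 lower at an unadjusted p under 0.05, against 21.7 each way by chance. The 6 measured stress-response genes had a median change of 1.53, with 0 of 6 higher over all genes and 4 of 6 higher adjusted over the list alone. The small heat-shock gene hsp16 had 3.36 ± 1.01 there (limma adjusted p = 0.235). The list's camera adjusted p was 2.45e-05 at the preset correlation but adjusted p = 0.3002 with an estimated correlation. Both measured subtelomeric genes, tlh2 and gal1 (1.98 ± 0.59, limma adjusted p = 0.235 over all genes), were higher adjusted over the list alone and 1 of 2 over all genes, and the list's adjusted p was 0.000101, or adjusted p = 0.183 with an estimated correlation. Non-coding RNA genes shifted by a median of 0.04 over 943 (adjusted p = 0.0123; adjusted p = 0.3002 with an estimated correlation), with 0 called. On the scan shared with the wild-type array, dpht1 replicate 1 was at least 2-fold higher over 8 antisense strands and lower over 2, and sense tlh2 was higher by 2.86. The 5 sense calls became 2 with median-centred processed signals, where signal columns and scaling both change, 2 with centring on sense probes, 0 with at least 5 probes per gene, 0 with the replicate block, and 0 or 1 without replicate 1 or 2. They became 49 against 0, 304 with scan as a random block and 0 with all annotated genes counted. The split of 2 higher and 3 lower became 1 and 3 under median centring, and antisense calls became 30 against 0, 48 with the scan block and 1 without replicate 1.

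Antisense RNA rose over 30 genes when pht1 and ago1 were both deleted, and fell over 1. The largest rises were over gem7 (2788470 to 2788887, facing the glutathione peroxidase gene gpx1) at 3.03 ± 0.43, the centaurin gene cnt5 (2181576 to 2184865) at 2.65 ± 0.56, the glycosyl hydrolase gene crr1 (1657057 to 1659076) at 2.48 ± 0.37, SPBC3E7.11c at 2.32 ± 0.37, SPBC1711.09c at 2.21 ± 0.47, the Golgi gene grp2 (2515248 to 2516757) at 2.19 ± 0.32, the phosphatidylserine decarboxylase gene psd1 at 2.024 ± 0.39 and the ubiquinone synthesis gene coq8 at 1.98 ± 0.39. Of the 30, 28 rose by at least 2-fold, and their median was 1.60. Antisense RNA over lsm1, an mRNA decapping gene, fell by 1.30 ± 0.16 (limma adjusted p from 0.0202 to 0.0482 for these 9 genes, 2 arrays against 1). Convergent genes held 25 of the 30. Over all 482 convergent genes the median change exceeded that of the other 387 by 0.17 (camera p = 5.33e-05; p = 0.184 with an estimated correlation). This difference became 0.55 with median-centred processed signals, 0.25 with median centring or sense-probe centring and 0.19 against 0. Median and sense-probe centring subtract different constants per array from the same ratios. The convergent difference is therefore the same under both by construction. Adjusted over the list alone, 42 convergent genes were higher, against 25 over all genes (adjusted p = 0.000533; adjusted p = 0.615 with an estimated correlation), and tandem genes lay lower (median -0.04, adjusted p = 0.00570; adjusted p = 0.492 with an estimated correlation). On the slide shared with the wild-type array, dpht1dago1 replicate 1 was at least 2-fold higher over 62 antisense strands and lower over 3, and the convergent difference was 0.13. The antisense count became 62 with median-centred processed signals, 48 with median centring, 5 with centring on sense probes, 199 against 0, 48 with the replicate block, 226 with the scan block, 51 without replicate 1 and 0 without replicate 2.

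On the sense strand of dpht1dago1, 9 genes rose and 10 fell. Sense RNA of hsp16 (2660139 to 2660992) rose by 5.84 ± 1.01, SPBC19C7.04c by 4.92 ± 0.86, tlh2 by 2.84 ± 0.41, SPBC725.03 by 2.78 ± 0.42, the kinase gene ppk31 by 2.74 ± 0.42, the sterol transfer gene osh2 by 1.52 ± 0.25, SPBC557.02c by 1.27 ± 0.21 and ubi4 by 1.16 ± 0.21. The lowest were cms1 at -2.13 ± 0.25, the cytochrome oxidase assembly gene coa1 at -1.73 ± 0.31, the GPI anchor gene gpi3 at -1.68 ± 0.26 and grp2 at -1.55 ± 0.29 (limma adjusted p from 0.0138 to 0.0364, 2 arrays against 1). The gene grp2 was among the called on both strands, higher on antisense and lower on sense. Stress-response genes had a median change of 2.17, with 2 of 6 higher over all genes and 4 of 6 adjusted over the list alone (adjusted p = 2.59e-05; adjusted p = 0.392 with an estimated correlation). The subtelomeric list had 1 of 2 higher both ways (median 1.72, adjusted p = 0.0473; adjusted p = 0.392 with an estimated correlation), and divergent genes lay lower (median -0.13, adjusted p = 0.0385; adjusted p = 0.526 with an estimated correlation). Among 943 non-coding RNA genes, 16 were higher over all genes and 13 adjusted over the list alone (adjusted p = 0.0214; adjusted p = 0.392 with an estimated correlation). The split of 9 and 10 was 7 and 2 with median-centred processed signals, 5 and 2 with median centring, and 6 and 2 with centring on sense probes. The 19 changed genes became 225 against 0, 2 with the replicate block, 321 with the scan block, 146 without replicate 1 and 2 without replicate 2.

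Whether the double mutant exceeded dpht1, or the sum of both single mutants, was tested directly. Against dpht1 (2 arrays against 2), antisense RNA rose over 1 gene, tac1, by 1.45 ± 0.19 (limma adjusted p = 0.0492), which was chosen for naming after its value was seen, and 118 strands were higher and 26 lower at an unadjusted p under 0.05. On the scan that both shared, replicate 1 of dpht1dago1 lay above replicate 1 of dpht1 by at least 2-fold over 30 strands and below it over 0, and the convergent difference was 0.12. In the dago1 single mutant (1 array), limma called 0 strands, with 25 antisense strands higher and 6 lower and 19 sense strands higher and 27 lower at an unadjusted p under 0.05. The cyclin-like gene clg1 had the highest antisense value, 2.52 ± 0.33 (limma adjusted p = 0.0542). The interaction of pht1 and ago1 loss gave 0 antisense calls by limma, with 19 strands higher and 8 lower at an unadjusted p under 0.05. The 1 call against dpht1 became 49 with median-centred processed signals, 0 with median centring, sense-probe centring, probes off other genes or all annotated genes, 33 with the replicate block, 165 with the scan block, 21 without dpht1dago1 replicate 1 and 0 without either dpht1 array.

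Loss of Clr4 raised RNA of the subtelomeric gene tlh2 and of centromere 2. Sense RNA of tlh2 rose by 5.02 ± 0.41 and its antisense RNA by 2.48 ± 0.23 (limma adjusted p = 0.00191 and 0.00408, 2 arrays against 1), and these were the only strands of coding genes called in dclr4, with 5 antisense strands higher and 9 lower at an unadjusted p under 0.05. The subtelomeric list, tlh2 with gal1, had a median antisense change of 1.39 with 1 of 2 higher over all genes and adjusted over the list alone (adjusted p = 1.06e-06, and 0.0297 with an estimated correlation). Its sense median was 2.93 (adjusted p = 7.21e-06; adjusted p = 0.102 with an estimated correlation). RNA from the 51487 bp that hold centromere 2 (1596745 to 1648231, between rpb1 and yox1) rose by 1.26 ± 0.15 on the plus strand and 1.36 ± 0.16 on the minus strand (limma adjusted p = 0.000131 over both strands of the 3 repeat regions examined). Of its 848 and 850 probes, 715 and 723 also match elsewhere. Ribosomal protein genes had a median sense change of 0.31 with 0 of 24 called (adjusted p = 0.000101; adjusted p = 0.434 with an estimated correlation), and stress genes 0.52 with 0 of 6 called and 1 of 6 adjusted over the list alone (adjusted p = 0.00451; adjusted p = 0.434 with an estimated correlation). Because tlh2 has 4 probes, a minimum of 5 probes left 0 calls on either strand, and sense-probe centring left 0 antisense calls. Over all annotated genes 3 antisense and 2 sense strands were called, and 2 sense strands with the scan block.

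Antisense RNA rose over 106 genes when pht1 was lost together with Clr4 and over 114 when its loss was combined with the rik1 mutation. In dpht1dclr4 3 genes fell beside the 106 that rose, led by nvj2 (2106331 to 2108978) at 4.04 ± 0.80, the elongator gene elp5 (2082409 to 2083643) at 3.77 ± 0.66 and cnt5 at 3.76 ± 0.65 (limma adjusted p from 0.0127 to 0.0206, 1 array). The 3 that fell, chosen for naming after their values were seen, were lsm1 at -1.51 ± 0.19, SPBC8D2.16c at -0.97 ± 0.26 and rbd3 at -0.92 ± 0.25 (limma adjusted p from 0.00688 to 0.0498). In dpht1rik1 114 rose and 26 fell, led by elp5 at 4.22 ± 0.66, cnt5 at 4.14 ± 0.65 and nvj2 at 3.96 ± 0.80, while antisense RNA over the MAP kinase kinase kinase gene byr2 fell by 2.41 ± 0.50 (limma adjusted p from 0.00858 to 0.0196). At least 2-fold rises made up 84 of the 106 and 95 of the 114, with medians of 1.53 and 1.52. Convergent genes were 85 of the 106 and 94 of the 114, and their median exceeded that of the other genes by 0.31 and 0.29 (camera p = 2.28e-07 and 1.17e-07; p = 0.105 and 0.0987 with an estimated correlation). The genes overlapped: 86 rose in both genotypes, against 13.9 for independent lists, and the changes correlated across 869 genes at r = 0.94, where 100 simulations of unchanged genotypes against the same wild-type array gave 0.50. The covariance exceeded the simulated one by 0.50. With 1 wild-type array the control could not be split, so part of the excess may come from it. Against each array's own wild-type RNA, without that array, the correlation was 0.93. On the slide and scan shared with dclr4 replicate 2, dpht1dclr4 was at least 2-fold higher over 89 antisense strands and lower over 13, and the convergent difference was 0.26. The interactions gave 0 antisense calls by limma, with 95 higher and 2 lower for clr4 and 97 higher and 19 lower for rik1 at an unadjusted p under 0.05, and smallest adjusted p of 0.0895 and 0.165. For clr4 the 0 became 6 against 0, 12 with the replicate block and 184 with the scan block, and for rik1 34 with the scan block. The counts of 106 and 114 became 48 and 68 with median-centred processed signals and 194 and 212 against 0, and that of dpht1rik1 became 205 with median centring. The dpht1rik1 split became 205 and 5 with median centring and 138 and 0 with sense-probe centring.

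On the sense strand few genes were called in these mutants. Both dpht1dclr4 and dpht1rik1 have 1 array, and the simulation of dalp13, also with 1 array, recovered 29.9% of 2-fold changes. Few calls therefore do not show that sense RNA stayed unchanged. In dpht1dclr4 tlh2 rose by 5.81 ± 0.48 and pht1 itself fell by 3.36 ± 0.42, a split of 1 and 1 that became 1 and 2 with median centring. In dpht1rik1 8 genes rose and 12 fell, among them hsp16 at 5.88 ± 1.16, tlh2 at 5.60 ± 0.48, cms1 at -2.25 ± 0.29 and gpi3 at -1.94 ± 0.30 (limma adjusted p from 0.00248 to 0.0477, 1 array). That split was 6 and 2 with median-centred processed signals, 5 and 4 with median centring and 10 and 1 with sense-probe centring. The iron-siderophore transporter gene str1 had 4.80 ± 1.07 there (limma adjusted p = 0.0560), with the wild-type array itself at -2.01. In the rik1 single mutant tlh2 was the only called gene, at 5.57 ± 0.48 sense and 2.40 ± 0.26 antisense (limma adjusted p = 0.00258 and 0.0151), and the antisense call was lost with median centring and with sense-probe centring. Centromere 2 RNA rose by 1.61 ± 0.18 and 1.70 ± 0.18 in rik1, 1.70 ± 0.18 and 1.88 ± 0.18 in dpht1dclr4, 0.87 ± 0.18 and 1.01 ± 0.18 in dpht1rik1, and 0.52 ± 0.15 and 0.56 ± 0.16 in dpht1dago1 on the plus and minus strands (limma adjusted p from 4.12e-05 to 0.0311). In dpht1 it was -0.04 ± 0.15 and -0.05 ± 0.16, with a limma adjusted p of 0.825, and in dago1 0.44 and 0.45 with 0.120.

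**Figure D2:**
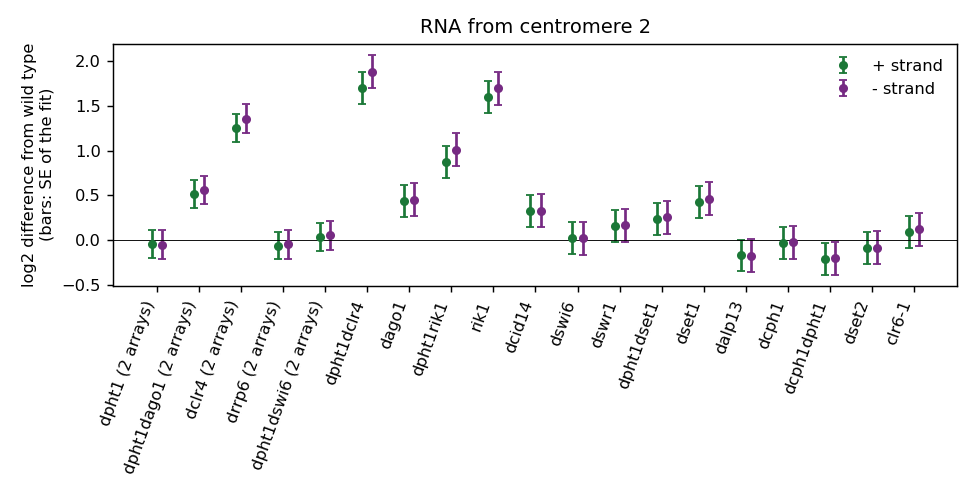
The log2 difference from wild type over centromere 2 (vertical axis) is plotted for 19 mutants on the plus and minus strands, with bars for the standard error of the fit. The values reach 1.70 and 1.88 in dpht1dclr4 and lie at -0.04 and -0.05 in dpht1.

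Loss of the exosome nuclease Rrp6 raised antisense RNA over 107 genes and lowered it over 28. It rose by 3.84 ± 0.69 over nvj2, 3.70 ± 0.62 over the mitochondrial ribosomal gene snr1 (2981002 to 2982440), 3.66 ± 0.57 over elp5, 3.36 ± 0.70 over the meiotic recombination gene rec15 (all 7 probes inside SPBC1711.15c, whose sense RNA they measure), 2.95 ± 0.47 over SPBC1711.09c, 2.88 ± 0.32 over grp2, 2.82 ± 0.56 over cnt5 and 2.59 ± 0.44 over mug93. It fell by 2.95 ± 0.62 over the F-box gene pof9, 2.19 ± 0.43 over byr2, 1.80 ± 0.32 over the autophagy gene atg2402 and 1.59 ± 0.32 over SPBC23G7.10c (limma adjusted p from 0.00454 to 0.0204, 2 arrays against 1). On the wild-type array itself pof9 antisense stood at 0.89. Of the 14 antisense probes of grp2, 5 lie inside ish1 on that strand. Convergent genes were 87 of the 107 and lay above the others by a median of 0.19 (camera p = 0.000273, and p = 0.225 with an estimated correlation). This became 0.42 with median-centred processed signals, 0.28 with median centring or sense-probe centring (the same by construction) and 0.21 against 0. Adjusted over the list alone 93 convergent genes were higher (adjusted p = 0.00273; adjusted p = 0.749 with an estimated correlation). Of the 30 genes that rose in dpht1dago1, 23 also rose in drrp6, against 3.69 for independent lists, and 52 of the 106 in dpht1dclr4 did, against 13.1. Their changes correlated at 0.71 and 0.75 across genes, with 0.66 and 0.57 in the simulations of unchanged genotypes and covariances 0.22 and 0.34 above the simulated ones. Against each array's own wild-type RNA the correlations were 0.68 and 0.73. The split of 107 and 28 was 48 and 4 with median-centred processed signals, 158 and 5 with median centring and 96 and 1 with sense-probe centring. The count was 70 for at least 2-fold, 216.00 against 0, 67 without replicate 1 and 35 without replicate 2.

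Some meiotic and stress genes rose on the sense strand in drrp6. All 3 measured targets of Mmi1, which marks meiotic RNAs for elimination, rose: the meiotic RNA-binding gene spo5 by 4.48 ± 0.35, the meiotic cohesin gene rec8 by 3.89 ± 0.32 and the meiotic transcription factor gene mei4 by 3.66 ± 0.26 (limma adjusted p = 0.000636 each, 2 arrays against 1). This list's adjusted p was 8.99e-06 (adjusted p = 0.125 with an estimated correlation), and all 3 were also higher adjusted over the list alone. Of 24 genes with meiotic symbols, which hold these 3, 9 were higher over all genes and 9 adjusted over the list alone (adjusted p = 0.000438; adjusted p = 0.223 with an estimated correlation). The non-coding meu3 was among them, at 5.17 ± 0.51. On the antisense strand mug93 and meu17 (1.88 ± 0.25, limma adjusted p = 0.00499) of this list rose, and the rise at rec15 is the sense signal of SPBC1711.15c given below. Of 6 stress genes 4 were higher over all genes and 5 adjusted over the list alone, including hsp16 at 4.42 ± 1.01, the nuclear envelope gene ish1 at 3.29 ± 0.53 and SPBC725.03 at 2.82 ± 0.42 (adjusted p = 0.000159; adjusted p = 0.223 with an estimated correlation). Other rises were lsd90 at 4.76 ± 1.11, SPBC19C7.04c at 3.595 ± 0.86 and SPBC1711.15c at 3.42 ± 0.70. The lowest were tlh2 at -2.71 ± 0.41, spf31 at -2.00 ± 0.31, the phosphatase gene pho2 at -1.83 ± 0.42 and the phosphoserine phosphatase gene ser2 at -1.74 ± 0.30 (limma adjusted p from 0.00271 to 0.0471 for the genes after mei4). On the wild-type array itself pho2 stood at 0.91. Of 943 non-coding RNA genes 97 were higher and 52 lower over all genes, and 106 and 59 adjusted over the list alone (adjusted p = 0.00276; adjusted p = 0.223 with an estimated correlation). Divergent genes lay lower by a median of -0.18 (adjusted p = 0.0471; adjusted p = 0.391 with an estimated correlation). In total 29 genes rose and 30 fell, and the split was 9 and 1 with median-centred processed signals, 29 and 6 with median centring and 28 and 3 with sense-probe centring. The 59 changed genes became 192 against 0, 32 with the replicate block, 104 with the scan block, 208 with all annotated genes, 4 without replicate 1 and 5 without replicate 2.

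When Swi6 was lost together with pht1, tlh2 and few other genes were called. On the sense strand limma had 28 strands higher and 64 lower at an unadjusted p under 0.05, against 21.9 each way by chance. Sense tlh2 rose by 4.03 ± 0.41 and antisense tlh2 by 2.48 ± 0.23, while cms1 fell by 1.94 ± 0.25 and pht1 itself fell by 2.61 ± 0.36 (limma adjusted p from 0.00410 to 0.0276, 2 arrays against 1). The subtelomeric list had 1 of 2 sense strands higher over all genes and 2 adjusted over the list alone (median 2.85, adjusted p = 0.000145; adjusted p = 0.172 with an estimated correlation), and 1 of 2 antisense strands both ways (median 1.43, adjusted p = 0.000528; adjusted p = 0.0951 with an estimated correlation). Ribosomal protein genes (median 0.37, adjusted p = 0.000936) and stress genes (0.86, adjusted p = 0.00229) had 0 called members and adjusted p = 0.479 with an estimated correlation for both. Against dpht1, antisense tlh2 was the only call, at 1.75 ± 0.18 (limma adjusted p = 0.0120, 2 arrays against 2), and the interaction gave 0 calls by limma with 2 higher and 2 lower at an unadjusted p under 0.05. In dswi6 (1 array) limma called 0 strands, with 3 antisense strands higher and 3 lower and 11 sense strands higher and 35 lower at an unadjusted p under 0.05. The antisense subtelomeric list had a median of 1.04 in dswi6, with 0 of 2 higher over all genes and 1 adjusted over the list alone (adjusted p = 2.68e-07, and 0.0249 with an estimated correlation). The dpht1dswi6 sense split of 1 and 2 was 1 and 1 with median-centred processed signals or sense-probe centring. A minimum of 5 probes or sense-probe centring left 0 antisense calls. Ratios against 0 gave 12 antisense and 15 sense calls, all annotated genes or either replicate left out gave 1 sense call, and the scan block gave 5. The call against dpht1 was lost with 5 probes, either centring, or without either dpht1 array or dpht1dswi6 replicate 1.

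Loss of Alp13 or Cph1 raised antisense RNA over the largest sets of genes among the 19 mutants. In dalp13 279 genes rose and 12 fell, with SPBC18H10.05 (1779254 to 1781985) at 3.84 ± 0.28, phs1 at 3.08 ± 0.25, lsd90 at 3.04 ± 0.44 and gpx1 at -1.54 ± 0.39. In dcph1 247 rose and 5 fell, with SPBC18H10.05 at 3.42 ± 0.28, the CCAAT-binding repressor gene php4 at 3.18 ± 0.30, lsd90 at 3.102 ± 0.44, gpx1 at -1.38 ± 0.39 and rip1 at -1.17 ± 0.24. Also lower there, and named after their values were seen, were gem8 at -1.13 ± 0.33, lam1 at -1.05 ± 0.24 and SPBC336.16 at -0.69 ± 0.22. In dcph1dpht1 250 rose and 14 fell, with SPBC18H10.05 at 3.57 ± 0.28, lsd90 at 3.31 ± 0.44, the cell-cycle transcription gene rep2 at 3.19 ± 0.21, gpx1 at -1.83 ± 0.39 and SPBC27.05 at -1.75 ± 0.24 (limma adjusted p from 0.000191 to 0.0462, 1 array each). Medians of the higher genes were 1.27, 1.23 and 1.24, and convergent genes were 147 of 279, 132 of 247 and 130 of 250, with convergent minus other medians of -0.06, -0.05 and 0.03. Loss of Set2 raised 64 genes and lowered 0, led by the G protein gene gpa1 at 2.38 ± 0.25, the MBF gene res1 at 2.31 ± 0.24 and the splicing gene prp1 at 2.16 ± 0.32 (limma adjusted p from 0.00211 to 0.00935; 171 higher and 10 lower at an unadjusted p under 0.05). In clr6-1 25 rose and 5 fell, with the cytochrome oxidase gene cmc1 at 3.56 ± 0.37, emc7 at 2.62 ± 0.41, SPCP20C8.02c at 2.27 ± 0.46 and the glycosylation gene alg2 at -1.77 ± 0.37 and rip1 at -1.28 ± 0.24. Also lower, and named after their values were seen, were SPBC8D2.16c at -1.23 ± 0.26, yhm2 at -1.16 ± 0.23 and lam1 at -1.16 ± 0.24 (limma adjusted p from 0.00432 to 0.0467 in clr6-1). Of the antisense probes, 13 of 14 at cmc1 lie inside the coding gene SPBC21D10.08c, whose sense RNA changed by 3.06 in clr6-1, 11 of 11 at rip1 lie inside ppa2, and 14 of 33 at alg2 lie inside his3. Of the genes that rose in dalp13, 231 also rose in dcph1, against 79.3 for independent lists, and 63 of the 64 in dset2, against 20.6. The correlations were 0.89 and 0.75, with 0.50 and 0.49 in simulations, and covariances lay 0.47 and 0.25 above the simulated ones. Against each array's own wild-type RNA the correlations were 0.90 and 0.77. Between dalp13 and drrp6 41 genes were shared, against 34.4, with a correlation of 0.16 against 0.58 in simulations and a covariance 0.05 above the simulated one. Removing pht1 from dcph1 gave an interaction with 0 calls by limma (7 higher and 15 lower at an unadjusted p under 0.05), or 9 higher with the scan block. On their shared slide and scan dcph1dpht1 was at least 2-fold higher than dcph1 over 6 antisense strands and lower over 2. The clr6-1 split was 55 and 3 with median-centred processed signals, 21 and 0 with median centring and 1 and 0 with sense-probe centring. Sense-probe centring gave 446 for dalp13, 430 for dcph1dpht1 and 0 for dset2, and median centring 378 for dcph1dpht1 and 23 for dset2. Median-centred processed signals gave 25 for dset2, ratios against 0 177 for dset2 and 101 for clr6-1, and the scan block 98 and 48. All annotated genes counted gave 38 for dset2 and 46 for clr6-1, and the replicate block gave 16 for clr6-1.

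**Figure D3:**
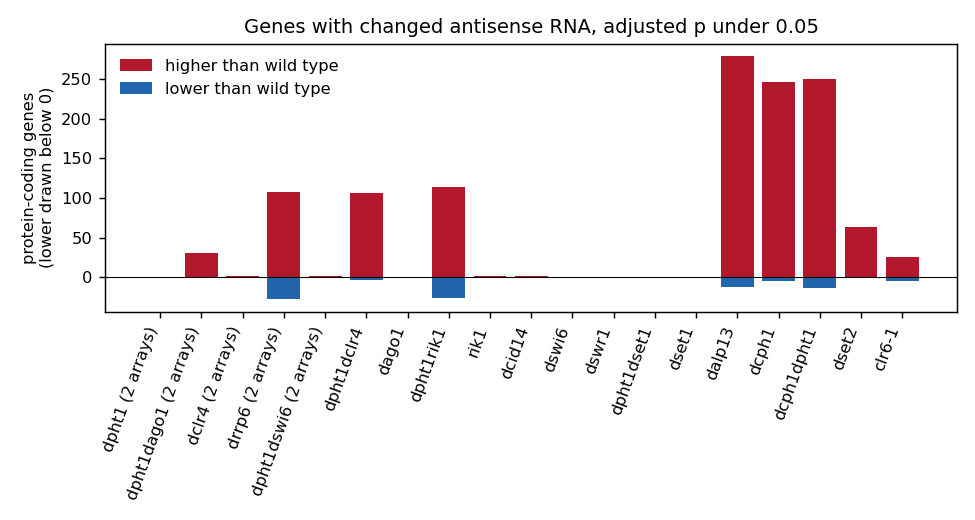
Bars give the number of protein-coding genes (of 869) whose antisense RNA was higher (above 0) or lower (below 0) than on the wild-type array at a limma adjusted p under 0.05, for 19 mutants. The counts run from 0 in dpht1 and dago1 to 279 higher in dalp13.

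Along the genes, the mean antisense change of dalp13, dcph1, dpht1dclr4 and drrp6 varied with position. In dalp13 the mean change was greatest in the third of 10 equal parts from the 5′ end, at 0.93 for non-convergent and 0.92 for convergent genes, and was -0.11 and -0.35 in the last part. In dcph1 the third part had 0.91 and 0.89 and the last 0.04 and -0.18. In dpht1dclr4 convergent genes had 0.46 in the fourth part and 0.15 in the last, and non-convergent genes at most 0.06. In drrp6 convergent genes peaked at 0.34 in the sixth part. These positional means carry no test.

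**Figure D4:**
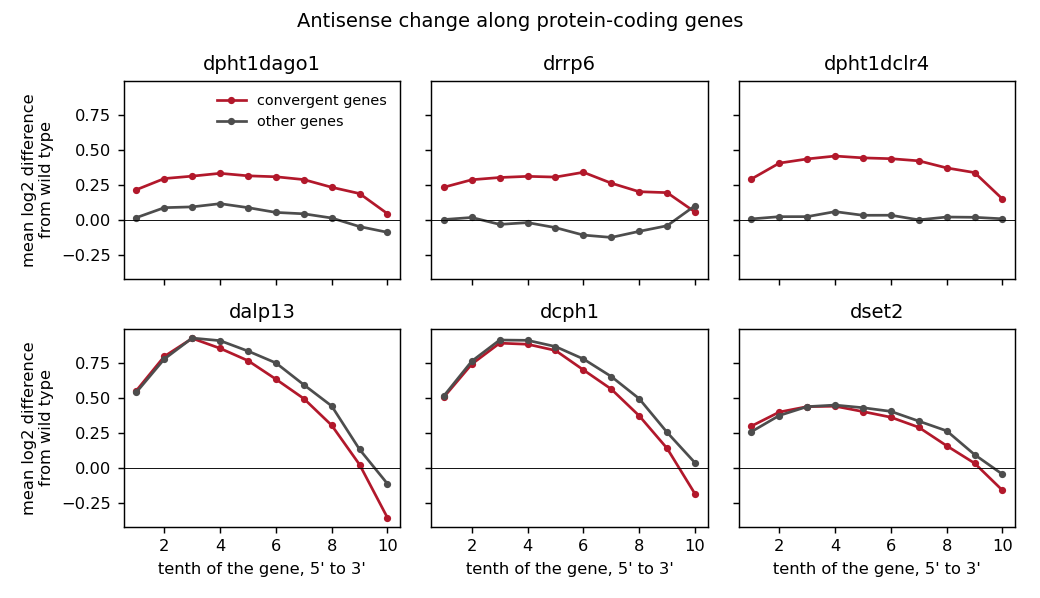
The mean log2 antisense difference from wild type (vertical axis) is drawn over 10 equal parts of the gene from 5′ to 3′ for convergent and other genes in 6 genotypes. In dalp13 the convergent and other lines peak at the third part (0.92 and 0.93) and end at -0.35 and -0.11, while in dpht1dclr4 they reach 0.46 and 0.06.

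Sense RNA of the genes with higher antisense RNA had a median change of -0.22 in dalp13, -0.10 in dcph1, -0.23 in dcph1dpht1, -0.19 in dset2, -0.39 in dpht1dago1 and -0.24 in drrp6. Over all 874 sense strands the medians were, in the same order, -0.10, -0.10, -0.21, -0.06, -0.105 and -0.11. In dcph1 and dcph1dpht1 these genes therefore lay close to the median of all genes. Across 866 genes sense and antisense changes had Pearson correlations from -0.16 to -0.03 and Spearman correlations from -0.17 to -0.01 in 9 genotypes, where genes are not independent replicates. Among all genes, dalp13 had 3 sense strands higher and 2 lower: the mitochondrial chaperone gene hsp78 at 3.88 ± 0.57, the thiamine synthesis gene nmt1 (chromosome 3) at 3.24 ± 0.23, SPBC28E12.02 at 2.031 ± 0.24, SPBC336.16 at -1.64 ± 0.23 and mcs2 at -1.36 ± 0.17. Of these nmt1, SPBC28E12.02 and mcs2 were named after their values were seen. In dcph1 4 rose and 9 fell, with nmt1 at 2.90 ± 0.23, meu17 at 2.061 ± 0.33, SPBC28E12.02 at 1.86 ± 0.24, mcp4 at 1.46 ± 0.25, SPBC18H10.05 at -2.21 ± 0.21 and yhm2 at -1.72 ± 0.28. In dcph1dpht1 10 rose and 45 fell, with ppk31 at 3.74 ± 0.48, nmt1 at 3.06 ± 0.23, cms1 at -2.33 ± 0.29 and izh2 at -1.81 ± 0.28. In clr6-1 23 rose and 22 fell, with hsp16 at 5.21 ± 1.16, hsp78 at 3.98 ± 0.57, the galactokinase gene gal1 at 3.79 ± 0.68 and SPBC18E5.01 at -2.34 ± 0.30 (limma adjusted p from 0.000547 to 0.0468, 1 array each). On the wild-type array itself hsp78 stood at -1.75 and SPBC18E5.01 at 0.95, and against their own wild-type RNA hsp78 had 2.14 in dalp13 and 2.23 in clr6-1. Of 24 meiotic-symbol genes 9 were higher in clr6-1 over all genes and 12 adjusted over the list alone (adjusted p = 0.00199; adjusted p = 0.283 with an estimated correlation). dset2 had 0 sense calls by limma, with 14 higher and 31 lower at an unadjusted p under 0.05. With median-centred processed signals, median centring and sense-probe centring, the splits were 4 and 0, 5 and 2, and 10 and 0 in dalp13. In the same order they were 1 and 1, 6 and 6, and 3 and 0 in dcph1, 5 and 4, 8 and 18, and 6 and 1 in dcph1dpht1, and 13 and 1, 15 and 2, and 13 and 1 in clr6-1.

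Antisense RNA over Tf2-10 (1965390 to 1969390), a retrotransposon whose probes nearly all match other copies (78 of 78 antisense and 72 of 75 sense), rose by 2.11 ± 0.28 in dalp13, 1.94 ± 0.28 in dcph1, 2.12 ± 0.28 in dcph1dpht1 and 1.38 ± 0.28 in clr6-1 (limma adjusted p from 0.000427 to 0.00731 over both strands of 3 repeat regions). Its sense RNA rose by 1.84 ± 0.48 in dalp13 and 1.49 ± 0.48 in dcph1 (limma adjusted p = 0.0163 and 0.0459). Antisense RNA over ribosomal protein genes had a median of -0.80 in dalp13, with 3 of 24 lower over all genes and 1 adjusted over the list alone (adjusted p = 1.13e-09; adjusted p = 0.447 with an estimated correlation). The third region, mat1-Mc, was not called in any genotype. Annotated non-coding RNA genes were higher in dalp13 (278 of 943 over all genes, 302 adjusted over the list alone, adjusted p = 1.30e-09; adjusted p = 0.0540 with an estimated correlation), dcph1 (244 of 943 over all genes, 263 adjusted over the list alone, adjusted p = 1.45e-11) and dcph1dpht1 (258 and 284, adjusted p = 4.30e-13). The dcph1 and dcph1dpht1 list calls held with an estimated correlation (adjusted p = 0.0356 and 0.0267). Non-coding genes that lie antisense to coding genes share probes with the antisense strands counted above. How far these list calls restate those counts was not tested. Of 399 list tests over all genotypes, 99 passed at the preset correlation and 5 with an estimated one. The 5 were the 2 just given and the antisense subtelomeric list in dclr4, dswi6 and rik1 (adjusted p = 0.0315 in rik1).

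The mutants dcid14, dswr1, dset1 and dpht1dset1 had 1 array each and few calls. In dcid14 antisense RNA rose over ero11 by 2.065 ± 0.28 and over tlh2 by 1.99 ± 0.26 (limma adjusted p = 0.0386), both named after their values were seen, while elp5, the highest at 4.01 ± 0.66, had a limma adjusted p of 0.0696. The antisense count of 2 became 1 with median-centred processed signals and 4 with median centring, and none was called with sense-probe centring. limma called 0 sense strands in dcid14 (16 higher and 35 lower at an unadjusted p under 0.05). In dswr1 limma called 0 strands (4 antisense higher and 13 lower, 17 sense higher and 29 lower at an unadjusted p under 0.05), and in dset1 also 0 (14 and 17 antisense, 17 and 44 sense). In dpht1dset1 sense RNA of meu17 rose by 2.45 ± 0.33 and pht1 fell by 3.04 ± 0.42 (limma adjusted p = 0.0386), with 0 antisense calls (26 higher and 23 lower at an unadjusted p under 0.05). That sense split of 1 and 1 became 1 and 2 with median centring and 0 and 1 with sense-probe centring. On the slide and scan that dpht1dset1 shared with dset1 it was at least 2-fold higher over 0 antisense strands and lower over 4, and the interaction gave 0 calls by limma (7 higher and 19 lower at an unadjusted p under 0.05), or 15 higher with the scan block.

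The remaining lists had few measured genes. The histone genes hhf2 and hht2 had 0 called members by limma over all genes in the 5 replicated genotypes. So did tas3 and pib1, the 2 measured members of the list written for heterochromatin and RNAi factors. In dpht1 their medians were 0.08 (adjusted p = 0.845) and -0.26 (adjusted p = 0.308), and in drrp6 0.61 and -0.40 (adjusted p = 0.302 for both), with tas3 at -0.71 ± 0.22 in drrp6, the only one lower adjusted over the list alone. The mating-type-specific gene mam1 lay between -0.68 and -0.35 on the sense strand in these genotypes with 0 called by limma. The Tf2 list had 1 gene with probes of its own, Tf2-10, at -0.67 in dpht1 (limma adjusted p = 0.567) and 0.36 in dpht1dago1. The siderophore transporter gene str1 stood for phosphate and iron uptake at 1.97 ± 0.93 in dpht1 (limma adjusted p = 0.414) and 3.595 ± 0.93 in drrp6 (limma adjusted p = 0.0609). On the wild-type array itself it stood at -2.01, and the dpht1 arrays had -0.34 and 0.27 against their own wild-type RNA. In all, 1 small nucleolar or nuclear RNA gene and 0 mating-type locus genes were measured.

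On the chromosome 2 ChIP arrays, H2A.Z was higher at gene starts than over gene bodies. The median log2 ratio of immunoprecipitate over input across 827 genes was 0.43 within 300 bp of the start, 0.18 over the body and 0.10 at the end, and 73.4% of genes had more H2A.Z at the start than over the body (median difference 0.20). On the wild-type array of the genome design the share was 51.4% of 4544 genes and the difference 0.02. Pol II ran the other way, with 0.08, 0.13 and 0.25 and 41.7% of genes higher at the start, and Rik1 had -0.07, -0.01 and 0.05. Rik1 was high over tlh2 (3.44, 123 probes) and centromere 2 (1.64, 1058 probes), where Pol II stood at -1.78 and -1.53 and H2A.Z at -0.84 and -0.65. Most of these probes match several places, and over the 8 and 260 with a single match Rik1 stood at 3.77 and 0.57, Pol II at -2.24 and -2.25 and H2A.Z at -1.42 and -1.46. At gene starts H2A.Z and Pol II correlated across genes at r = -0.43 (Spearman -0.38). H2A.Z correlated with the sense change in dpht1dago1 at -0.42 (Spearman -0.43), in dpht1rik1 at -0.37 (Spearman -0.37) and in dpht1 at -0.19 (Spearman -0.15). In mutants that keep pht1 the values were -0.27 (Spearman -0.29) in drrp6, -0.18 (Spearman -0.14) in dalp13 and -0.007 (Spearman 0.02) in dcph1. The negative values were thus not confined to pht1 mutants, and all these changes share the wild-type array. With the antisense change in dpht1dago1 H2A.Z had r = 0.02 (Spearman 0.01), and 45 such correlations were computed. Convergent genes had a median of 0.41 at the start and other genes 0.49. Each array stands alone, with no replicate or test, and genes are not independent replicates. With normexp the start-minus-body difference of H2A.Z was 0.32 and that of Rik1 -0.15, against -0.07.

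Msc1, a partner of the Swr1 remodeller, was examined on the genome design. H2A.Z had a median of 0.26 at the starts, 0.17 over the bodies and -0.15 at the ends of 4544 genes in wild type and -0.08, 0.07 and -0.09 over 4543 genes in dmsc1. At the start 70.5% of 4545 genes were lower in dmsc1, with a median difference of -0.33. The spread of the log2 ratio over probes was 0.75 in wild type and 0.39 in dmsc1, and the arrays correlated at r = 0.71 across probes. There was 1 array of each kind and no test.

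**Figure D5:**
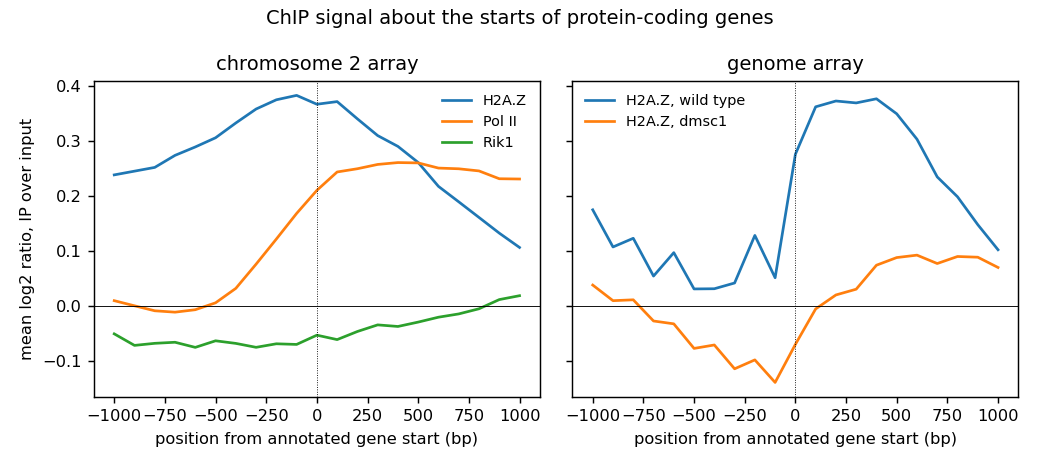
The mean log2 ratio of immunoprecipitate over input (vertical axis) is drawn by distance from the annotated gene start, from -1000 to 1000 bp, for Pol II, H2A.Z and Rik1 on chromosome 2 and for H2A.Z in wild type and dmsc1 on the genome design. H2A.Z reaches 0.38 at -100 bp on chromosome 2, and on the genome design it reaches 0.38 at 400 bp in wild type and lies at -0.14 at -100 bp in dmsc1.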

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

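The tests of copying of sense RNA, of the slide of dalp13 and of the facing gene's RNA were set before their results were seen, and those of scaling, of probes inside other genes, of the slide of dcph1, of more copying at unchanged sense RNA and, for convergent and stress genes, of the wild-type array, together with the interactions at convergent genes, were chosen after.

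At the preset correlation only, the rise of antisense RNA at convergent over other genes differed between pht1 loss in wild type and in 3 mutant backgrounds. Of the genotypes involved, dago1, dpht1dclr4, dpht1rik1, rik1 and wild type had 1 array each. The interaction was 0.13 (log2) for dpht1dago1 with dago1 (camera adjusted p = 0.000116), 0.27 for dpht1dclr4 with dclr4 (7.28e-08) and 0.33 for dpht1rik1 with rik1 (4.37e-10), over 482 convergent and 387 other genes. With an estimated correlation between genes the adjusted p was 0.373, 0.258 and 0.258, so none held there. The same contrast was 0.01 with dswi6 (adjusted p = 0.398), -0.04 with dset1 (0.362) and 0.01 with dcph1 (0.878). The convergent difference was 0.02 in dpht1, 0.01 in dago1, 0.04 in dclr4 and 0.0045 in rik1 alone, and 0.17, 0.31 and 0.29 in the doubles.

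Signal also came from probes outside annotated genes, which enter none of the gene values. Of 4653 such probes, 33.3% (median over 25 arrays, range 27.7 to 56.3) lay well above background in wild-type RNA, against 1.38% of 507 negative control spots (range 0.394 to 2.17).

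Antisense RNA over convergent genes in dpht1dago1 and drrp6 was set against technical explanations. Probes that lie inside another annotated gene could carry that gene's own RNA, but without them the smaller of the differences between convergent and other genes was 0.20, so these probes do not account for it. More RNA from the facing gene's own strand could run into the convergent gene. The facing genes' sense RNA had a median change of -0.0414 in dpht1dago1 (SD 0.77, 25 genes) and -0.10 in drrp6 (SD 0.88, 87 genes). The antisense medians were 1.59 and 1.30. These values bear only on a rise of RNA over the facing gene itself. They cannot test RNA that runs past its 3′ end without such a rise. Across 478 convergent pairs antisense and facing sense changes correlated at r = 0.19 in dpht1dago1 and 0.10 in drrp6. The single wild-type array could also create the convergent difference. Without that array, against each array's own wild-type RNA, the differences were 0.19 and 0.21 (camera p = 4.84e-06 and 5.47e-05 at the preset correlation). With that array they were 0.17 and 0.19, and camera p was 0.184 and 0.225 with an estimated correlation. That setting was not run without the array. That these genotypes hold more antisense RNA at convergent genes remains a hypothesis, which further replicate arrays would test.

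Antisense RNA over many genes in dalp13, dcph1 and dcph1dpht1 could be cDNA copied from sense RNA during labelling. More sense RNA to copy does not account for it, as the highest of the 3 median sense changes of these genes was -0.10. More copying at unchanged sense RNA would act most where sense RNA is most abundant. Among the 25% of genes with the most sense RNA in wild type, the highest share with raised antisense RNA was 16.7% (95% interval to 22.3%), against at least 32.9% (from 29.3%) of the 650 others. Scaling within the array could create it, but the lowest of the 9 counts under the other scalings was 236. The slide of dalp13 could also be the source, but the drrp6 array on that slide differed from drrp6 on another slide by a median of -0.0284 (SD 0.25) over the 279 genes, against 1.27 in dalp13. The arrays of dcph1 and dcph1dpht1 share a slide and a scan with 0 arrays of other genotypes, so no array tests that slide directly. An effect confined to it would leave their genes unchanged elsewhere, but against each array's own wild-type RNA these genes had medians of 1.34 and 1.31 in dalp13 (SD 0.58 and 0.63) and 0.63 and 0.62 in dset2 (SD 0.51 and 0.52), on other slides and scans. A scaling cause stays open. So does the hypothesis that these genotypes hold more antisense RNA inside genes, with 1 array each, which replicate arrays would test.

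Stress-response genes lay above wild type in most mutants, as with hsp16, which ran from -0.47 in dswr1 to 5.78 in dpht1dago1 replicate 2 against each array's own wild-type RNA. Low levels on the single wild-type array could produce this, but against each array's own wild-type RNA the 6-gene list still had a median of 0.84 over 24 mutant arrays (range -0.47 to 2.49), with 19 above 0 and 22 above the wild-type array at -0.27. No camera test of this list passed with an estimated correlation between genes. A stress that the cultures met differently was not tested and stays open.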

How the results depend on the processing

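Centring on sense probes, antisense probes off other genes and counts over all annotated genes were tests chosen after seeing the data, as was running the planned settings on the single-array mutants, the pht1 deletion check and the gene lists, and the rest were planned. Over the settings, 252 values for comparisons stayed the same, 106 moved, 4 newly passed the threshold and 3 turned sign. Counts stayed the same if within 1.5 times, and convergent differences if they kept direction and side of the threshold. The pht1 value had to stay within its spread, and ChIP values had to be identical. Among the 3 is the dpht1 convergent difference under both median and sense-probe centring, which give it the same value by construction. Of values for single genes 1781 kept direction and side of the threshold, 186 no longer passed, 46 newly passed and 1 turned. Except where a setting's construction shows it, the cause was not tested. Weak signal limits antisense values, whose median intensity in wild-type RNA was 103 against 1676 for sense strands. The series tables could not serve as a setting for expression, because they list only spots past a scanner p-value, and slide as a random block was not run, because no correlation could be estimated. Dropping the filter on dim probes moved none of these values past 1.5 times.

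Against 0 in place of the wild-type array, which removes that array's spread, antisense calls were 30 in dpht1, 199 in dpht1dago1, 216.00 in drrp6, 12 in dpht1dswi6, 194 in dpht1dclr4, 212 in dpht1rik1, 177 in dset2 and 101 in clr6-1, sense calls 49, 225, 192 and 15 in dpht1, dpht1dago1, drrp6 and dpht1dswi6, single-array interactions 6 (all dpht1dclr4), all single-array calls 1746 (1088 otherwise), the convergent difference in dclr4 0.0398 and passing, and str1 in dswi6 -0.22, a changed sign.

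With the processed signals, median centred in place of normexp and loess so that both changed, antisense calls were 62 in dpht1dago1, 48 in drrp6, 48 in dpht1dclr4, 68 in dpht1rik1, 25 in dset2, 55 in clr6-1 and 49 for dpht1dago1 against dpht1, sense calls 2, 9 and 10 in dpht1, dpht1dago1 and drrp6, the convergent difference in dclr4 0.17 and passing, and the highest pht1 value on a deletion array -2.85 (-2.36 otherwise). With median centring in place of loess alone, antisense calls were 48 in dpht1dago1, 205 in dpht1rik1, 378 in dcph1dpht1, 23 in dset2, and 0 for dpht1dago1 and 0 for dpht1dswi6 against dpht1, sense calls 7 and 35 in dpht1dago1 and drrp6, and the convergent difference in dpht1 turned to -0.0095. Loess kept the median of all strands within -0.06 to 0.09 of 0, while median centring moved it to -0.25 in dset1 and the median-centred processed signals to 0.36 in dcph1.

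With centring on sense probes, which moved that median to 0.68 in dcph1dpht1 and -0.23 in dswr1, antisense calls were 5 in dpht1dago1, 0 in dclr4, 0 in dpht1dswi6, 446 in dalp13, 430 in dcph1dpht1, 0 in dset2, 1 in clr6-1, and 0 for dpht1dago1 and 0 for dpht1dswi6 against dpht1, sense calls 2, 8 and 31 in dpht1, dpht1dago1 and drrp6, and the convergent difference in dpht1 -0.0095, a changed sign. With antisense probes off other genes the convergent difference in dclr4 was 0.0424 and passing, and dpht1dago1 against dpht1 had 0 calls. Over all annotated genes, antisense calls were 3 in dclr4, 38 in dset2, 46 in clr6-1 and 0 for dpht1dago1 against dpht1, and sense calls 0 in dpht1, 2 in dclr4, 208 in drrp6 and 1 in dpht1dswi6.

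At least 2-fold left 70 antisense calls in drrp6 and 165 in dcph1dpht1. At least 5 probes left 0 sense calls in dpht1, where cms1 and ely5 stayed at -1.85 and -1.37 (limma adjusted p = 0.0616 and 0.0671), and, by removing tlh2 with its 4 probes, 0 antisense and 0 sense calls in dclr4, 0 antisense calls in dpht1dswi6 and 0 against dpht1.

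The replicate block gave 48 antisense calls in dpht1dago1, 16 in clr6-1, 33 for dpht1dago1 against dpht1, 12 in single-array interactions (all dpht1dclr4), and 0, 2 and 32 sense calls in dpht1, dpht1dago1 and drrp6. The numbers do not pair the arrays: over 6 pairs of 4 genotypes the correlations of deviations ran from -0.66 to 0.48, with 2 above 0.1. Scan as a random block, with a correlation of 0.83 estimated from 1 pair, gave antisense calls of 48 in dpht1, 226 in dpht1dago1, 98 in dset2, 48 in clr6-1, 165 for dpht1dago1 against dpht1 and 242 in single-array interactions (184 in dpht1dclr4), and sense calls of 304, 321, 2, 104 and 5 in dpht1, dpht1dago1, dclr4, drrp6 and dpht1dswi6.

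Leaving out each replicate, with the lone array assumed to vary like the others, gave ranges of 0 to 1 antisense and 0 to 1 sense calls in dpht1 (convergent difference 0.01 to 0.05), 0 to 51 and 2 to 146 in dpht1dago1 (0.13 to 0.22), 1 to 1 and 1 to 1 in dclr4 (0.04 to 0.04), 35 to 67 and 4 to 5 in drrp6 (0.14 to 0.23), and 1 to 1 and 1 to 1 in dpht1dswi6, where the convergent difference was -0.0112 without replicate 2 and 0.0621 and passing without replicate 1. Calls against dpht1 ranged from 0 to 21 in dpht1dago1 and 0 to 1 in dpht1dswi6, and interactions gave 0.

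For ChIP, normexp gave start-minus-body differences of 0.32 for H2A.Z, -0.0561 for Pol II and -0.15 for Rik1 and a dmsc1 difference of -0.40, and a window of 150 bp gave 0.19, -0.0583, -0.065 and -0.33. With 1 array the spread between replicates is unknown, and the series table gave the same values.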

Other observations

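The counts of non-coding genes and the shares of probes outside genes come from tests chosen after seeing the data, and the correlations were planned.

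Annotated non-coding genes changed in several mutants. Of 948 sense strands of such genes, 106 rose and 59 fell in drrp6, with meu3 on chromosome 3 (41985 to 42728) at 5.17 ± 0.51, SPNCRNA.5922 at 4.24 ± 0.49 and SPNCRNA.5494 at 3.93 ± 0.68 (limma adjusted p from 0.00282 to 0.00941, 2 arrays against 1). SPNCRNA.5494 (2107586 to 2108756, plus strand) lies antisense to nvj2. In dpht1dago1 13 rose, among them SPNCRNA.5282 (1657132 to 1659194) at 2.48 ± 0.38 (limma adjusted p = 0.0386), which lies antisense to crr1, and 0 fell. In dclr4 the only called non-coding gene was SPNCRNA.6657 (4536239 to 4537492) near the chromosome end, at 2.82 ± 0.27 (limma adjusted p = 0.00608). The largest sets were in dalp13 (301 higher, 45 lower), dcph1dpht1 (283 and 51) and dcph1 (263 and 22), and dset2 had 107 and 4. Where such a gene lies antisense to a coding gene, its probes also enter that gene's antisense value. These counts are therefore not separate from the antisense counts. In dpht1 limma called 0, with 42 higher and 9 lower at an unadjusted p under 0.05.

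In drrp6 15.02% of 4639 probes outside annotated genes were at least 2-fold higher and 5.73% lower, and in dpht1dclr4 9.41% of 4635 were higher and 3.19% lower. In dalp13 4.37% of 4628 were higher and 12.5% lower, and in dcph1dpht1 3.56% were higher and 10.4% lower. These shares carry no test.

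At gene starts on chromosome 2 the antisense change in dalp13 correlated across 823 genes with H2A.Z at r = 0.26 (Spearman 0.26) and with Pol II at r = -0.31 (Spearman -0.31). For dcph1 the values were 0.15 (Spearman 0.17) and -0.21 (Spearman -0.24). Genes are not independent replicates and each ChIP array stands alone.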
